A study of Mus musculus with 26 samples.

How the data were processed

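The study measured mRNA 3′ ends by sequencing in 26 libraries of mouse brown adipose tissue: 11 of sorted macrophages and 15 of ribosome immunoprecipitates, inputs and an IgG control. Groups were taken from the sample titles and characteristics. Sorted cells came from enzymatic digestion and carried CD11b, F4/80, CD64, CD14, MerTK and MHC class II without Ly6C, per the labels. The submitters' processing notes name bcl2fastq, HISAT 0.1.5 and HOMER and the mm9 build, without roles or order; the gene models and counting options are not given in the sources used here. A GRCm38 reference was at hand, which is another build, so no coordinates are printed.

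The authors deposited 2 tables with 24421 genes each, 1 of the sorts and 1 of the ribosome libraries. Their unit is a normalized signal, reads per gene scaled to 10000000 mapped reads, per the file headers for the ribosome table and from the values for the sorts. The header of the ribosome table names its reads as UMI reads; whether molecular identifiers were used for the sorts is not stated. Each deposited signal value is a whole multiple of what 1 read is worth in that library, so whole reads could be recovered: 100% of values lay within 0.05 reads of a whole number. Mapped reads per library, the number that sets the precision of low genes, are 10000000 divided by the value of 1 read. In the smallest library, wild-type immunoprecipitate 3, 3 reads correspond to 55.4, and in the largest, dTomato-positive sort 8, to 3.84. Intervals and such floors cover counting error only. The tables were scaled separately, so tests were run within a table.

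The design fixed before the data were examined used edgeR on counts, with limma-trend on log2(value + 1) in case the tables held normalized values. They did, so limma was the test, after removing low genes with edgeR's filterByExpr (minimum 10 recovered reads), with robust empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale. There 1 read was worth 1.28 to 18.5, so libraries without a read move the fold changes of low genes by large steps. Such fold changes can be too large or too small. Against positive cells, T, B and NK cell genes had a median log2 of 5.22, and 4.19 by edgeR. Erythroid genes had 4.51, and 5.52 by edgeR. The dTomato sorts were fitted with their 8 libraries, the CX3CR1 sort with all 11 sorted libraries, the genotype in each fraction with its 7 libraries, and the immunoprecipitate against input and the difference of genotype effects with 14. Gene lists, written before the data were examined and 32 in number with at least 3 tested members, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison; calls that held with an estimated correlation were limited to the alternative activation list in the dTomato sorts. Matched random lists gave percentiles for the IgG library. Replicates of each group were compared before averaging, and no pair differed as little as sampling noise allows (chi-square per degree of freedom 3.63 to 35.0).

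Named genes followed a rule fixed beforehand: Mecp2, Cx3cr1, Rpl22 and Plxna4; up to 10 of the largest rises and falls among genes past the threshold whose groups did not overlap and whose level was sufficient; and members of the lists, up to 4 per list with a call and 2 from a list without. Predicted, RIKEN, microRNA and small nucleolar genes were left out of the rises and falls. The clock genes in the closing section outside this rule were chosen after the data were seen.

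Each fit was first tested on simulated data, 5 runs per comparison with 200 changed genes. With counts drawn per mapped read, which is the unit of the tables, the share of false calls was 3.35% for the dTomato sorts, 6.61% and 5.36% for the CX3CR1 sort against positive and negative cells, 3.68% for immunoprecipitate against input, 2.77% and 3.45% for the genotype in immunoprecipitate and input, and 4.45% for the difference. Recovery of 4-fold changes was 60.8%, 53.8%, 55.4%, 92.8%, 83.0%, 96.4% and 52.0% in that order, and of 2-fold changes 14.2%, 8.4%, 8.2%, 53.8%, 15.4%, 49.2% and 3.8%. When counts were drawn per read in genes instead, so that the share of reads in genes differed between groups with no gene changed beyond the set, immunoprecipitate against input gave 5931 false calls a run (97.6% of calls, unchanged genes at a median log2 of -0.91). The share of false calls in that drawing was 9.14% and 8.73% for the CX3CR1 sort against positive and negative cells, 8.16% and 4.72% for the genotype in immunoprecipitate and input, 2.81% for the dTomato sorts and 2.01% for the difference, and unchanged genes lay at a median log2 of 0.19, 0.18 and 0.34 for the first 3 and 0.37 for the difference between genotype effects. The call counts of immunoprecipitate against input therefore hold only for the deposited scaling. In both drawings each gene was drawn independently of the others, without differences between libraries that many genes share. The real libraries have such a structure, so these shares of false calls and recoveries need not hold for them.

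Alternatives were quantile normalization, a pseudocount of 0.1, no filter on low genes, a 2-fold minimum, each library left out in turn, other sets of libraries in the fit, the number in the titles as a block, a brown adipocyte covariate, and, added after seeing the data, edgeR and DESeq2 on the recovered reads, a pseudocount of 10, scaling to gene reads without Rn45s, centring on macrophage-restricted transcripts, the share of reads in genes as a covariate, and fits without the libraries most in doubt. The IgG library entered no test. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.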

Results

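Messenger RNA 3′ ends were counted in 26 libraries from mouse brown adipose tissue, the fat depot that burns lipid to make heat. Macrophages sorted by a shared set of surface markers gave 11 libraries: 4 from dTomato-positive cells, 4 from dTomato-negative cells of the same reporter line, in which tamoxifen-inducible Cre under the Cx3cr1 promoter marks cells, and 3 from a CX3CR1-cre line. The other 15 came from mice in which ribosomes of Cx3cr1-expressing cells carry a haemagglutinin (HA) tag: 4 HA immunoprecipitates from Mecp2 knockout and 3 from wild-type mice, whole-tissue inputs under the same numbers (4 and 3), and 1 immunoglobulin G (IgG) control from a knockout. Mapped reads per library ran from 2607056 to 7821449 in the dTomato sorts, 3072120 to 4219164 in the CX3CR1 sort, 541590 to 1061868 in wild-type and 1114530 to 1384658 in knockout immunoprecipitates, 813188 to 1465192 in wild-type and 578118 to 799913 in knockout inputs, and 1750279 in the IgG library. Values are reads per 10000000 mapped reads, as mean ± SD. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

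Mecp2, the targeted gene encoding a methyl-CpG binding protein, was measured in every library first. In the wild-type immunoprecipitates it stood at 348, 211 and 406, and in the knockout ones at 67.5, 26.9, 86.7 and 91.2, from 3 to 12 reads each. The wild-type inputs gave 282, 225 and 234 and the knockout inputs 104, 89.9, 37.5 and 50.2. The IgG library held 68.6. Sorted macrophages carried 468 ± 34.5 (n = 3) in the CX3CR1 sort, 556 ± 121 (n = 4) in dTomato-positive and 491 ± 110.5 (n = 4) in dTomato-negative cells. Every knockout library therefore lay below every wild-type library of its fraction. Where the 3′ tag of Mecp2 lies relative to the deleted part is not given in the sources used here; a tag outside that part would check nothing.

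The dTomato sorts ask how macrophages marked by Cx3cr1-driven recombination differ from unmarked macrophages of the same gate. Cx3cr1, the fractalkine receptor gene, was 4.64-fold higher in the dTomato-positive cells, at 720 ± 159 (SD, n = 4) against 153 ± 23.6 (SD, n = 4). Genes of alternative activation and tissue residence were lower in the positive cells: Retnla, a secreted marker of alternative activation, stood at 14830 ± 1733 against 84660 ± 12360, and Folr2, a folate receptor, at 2918 ± 615 against 14980 ± 4145. H2-Aa, a class II presentation gene, reached 265100 ± 48630 against 129200 ± 8020, a call that quantile normalization ended, and Ciita, the class II transactivator, 1674 ± 364 against 594 ± 56.1. Mecp2 and Rpl22 differed by less than the spread between replicates, with log2 fold changes of 0.18 ± 0.27 (SE) and -0.03 ± 0.19.

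By limma with Benjamini-Hochberg adjustment, 220 of 10280 tested genes differed, 85 higher and 135 lower in the positive cells, and DESeq2 called 410. Of the 17 tested alternative activation and resident genes, 11 fell and none rose among the calls over all genes, and 12 fell when adjusted over the list alone (camera adjusted p = 6.87e-23, and adjusted p = 0.00705 with an estimated correlation). The C-type lectin genes Cd209d and Cd209f of that list were 11.8-fold and 10.8-fold lower (limma adjusted p = 1.57e-07 and 6.55e-08). Their neighbours Cd209b and Cd209a were 14.1-fold and 8.16-fold lower, and Cd209g stood at 292 ± 165 against 3472 ± 1326; these paralogs are alike in sequence and can share reads, so each value is uncertain. The complement gene Cfb fell from 1207 ± 316 to 93.3 ± 34.0 and the ficolin gene Fcna from 6365 ± 2196 to 791 ± 344.

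Of 11 tested class II presentation genes 6 rose, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.76e-06, but adjusted p = 0.251 with an estimated correlation). H2-Eb1 rose 2.22-fold and H2-Ab1 1.90-fold (limma adjusted p = 0.00108 and 0.0202). Leaving out negative sort 5 or 6 ended the call of H2-Ab1, and quantile normalization ended those of H2-Aa and H2-Ab1. Microglia-type genes also moved, 3 of 11 higher and, adjusted over the list alone, 3 higher and 1 lower (camera adjusted p = 0.0303, and adjusted p = 0.251 with an estimated correlation), a list test lost without positive sort 5 or 8 or negative sort 7 or 8. Macrophage core genes rose in 1 of 24 cases, 4 adjusted over the list alone (camera adjusted p = 0.0306, lost without positive sort 5 or 8 or negative sort 7, and adjusted p = 0.687 with an estimated correlation). Tgfbr1, a TGF-β receptor, rose 3.19-fold to 1286 ± 132. Hexb, a lysosomal hexosaminidase, rose 2.47-fold, a call lost without positive sort 6. The largest rises by fitted fold included Cadm1, an adhesion molecule (10.5-fold, to 466 ± 143), Col4a2, a basement membrane collagen (8.99-fold), Zmynd15 (7.97-fold), Lilra5 (6.84-fold, to 1927 ± 367), Arap3 (6.65-fold) and Pdgfb, a growth factor for pericytes (5.57-fold). Cd72 rose 5.52-fold and Cd79b, a B cell receptor chain, 4.13-fold, to 702 ± 69.8.

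Iron handling genes fell in 2 of 10 cases, 3 when adjusted over the list alone (camera adjusted p = 0.00265, and adjusted p = 0.156 with an estimated correlation). These were Tfrc, the transferrin receptor (3.13-fold, limma adjusted p = 0.00245), and Hmox1, haem oxygenase (1.94-fold, adjusted p = 0.0101). The lysosomal protease Ctsl fell 2.13-fold. Inflammatory genes rose in 2 of 14 cases, 3 adjusted over the list alone (camera adjusted p = 0.0178, and adjusted p = 0.690 with an estimated correlation); the chemokine Ccl3 and the inflammasome sensor Nlrp3 were 2.77-fold and 3.19-fold higher, calls lost without positive sort 6 or 8 or negative sort 7, that of Ccl3 also without negative sort 5, and that of Nlrp3 also without positive sort 7 or negative sort 6 or 8 and without the filter on low genes. The list test of inflammatory genes was lost without positive sort 6 or negative sort 5, 7 or 8. Erythroid genes fell in 2 of 6 cases, 4 adjusted over the list alone (camera adjusted p = 7.01e-07, and adjusted p = 0.271 with an estimated correlation), with Hbb-b2, a globin that shares reads with its near-identical copy, at 11.9 ± 7.48 against 356 ± 306, a call lost without positive sort 5, 6 or 7 or negative sort 5 or 6. Plxna4, a plexin receptor for semaphorins, stood at 238 ± 64.2 in positive and 113 ± 50.9 in negative cells, which passed the test among the 4 genes fixed beforehand (limma adjusted p = 0.0302) but not over all genes (adjusted p = 0.240).

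**Figure D1:**
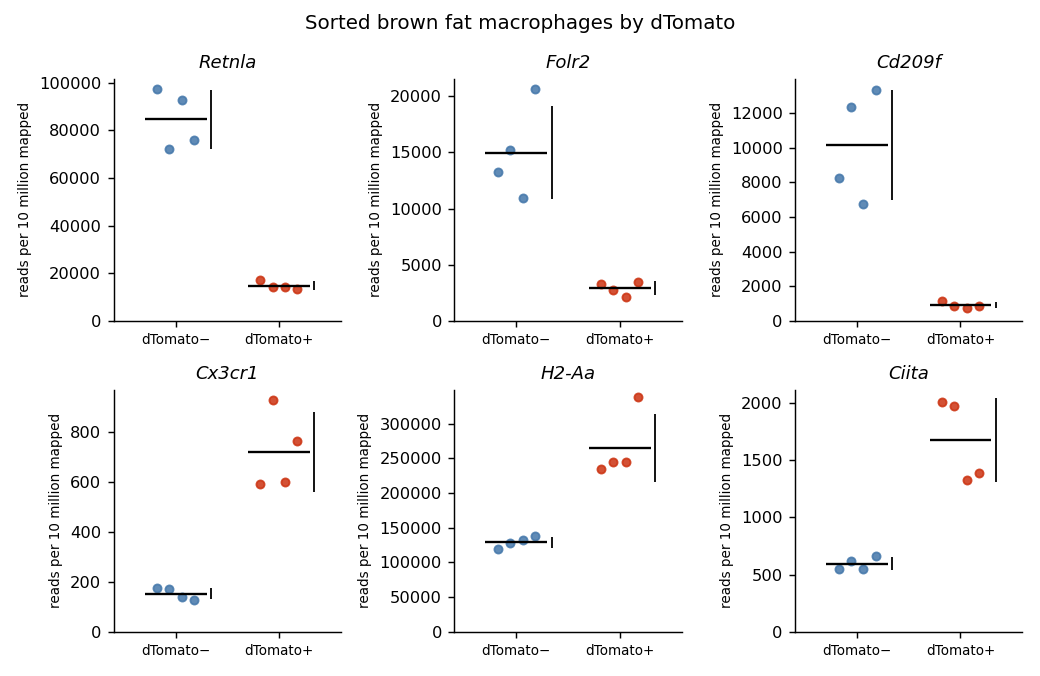
Reads per 10000000 mapped reads (vertical axes, linear) of 6 genes in each dTomato-negative and dTomato-positive sort; points are libraries, horizontal lines means and vertical lines ± 1 SD (n = 4). The groups do not overlap for any of the 6 genes, with Retnla, Folr2 and Cd209f lower and Cx3cr1, H2-Aa and Ciita higher in positive cells.

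The macrophages of the CX3CR1-cre line were set against both dTomato sorts, which differ from them in mouse line and in the use of dTomato in the gate. Against the dTomato-positive cells, single genes of alternative activation were higher in the CX3CR1 sort: Folr2 stood at 26140 ± 12940 (SD, n = 3) against 2918 ± 615 (SD, n = 4), and Ccl24, an eosinophil chemokine, at 5402 ± 2005 against 858 ± 224. Cd209f and Cd209g, paralogs that can share reads, stood at 25000 ± 16850 and 7281 ± 3868 against 915 ± 181 and 292 ± 165. H2-Ab1 was lower, at 83260 ± 26370 against 192600 ± 53740, as were Irf8, a transcription factor of dendritic cells and macrophages (1599 ± 228 against 3235 ± 810), and Ccr2, the receptor that brings in monocytes (1010 ± 294 against 2896 ± 745). Cx3cr1 itself was uneven among the CX3CR1 sorts, at 1850, 202 and 239.

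Here 1325 of 11077 tested genes differed by limma with Benjamini-Hochberg adjustment, 834 higher and 491 lower in the CX3CR1 sort. The median of all genes lay 0.21 higher (log2) under the deposited scaling, and the balance depended on it: edgeR with its own scaling called 1248, 588 higher and 660 lower, and scaling to reads in genes called 1229, 511 higher and 718 lower. Log2 fold changes against the dTomato-positive sort are therefore given relative to that median. Of 18 alternative activation and resident genes 11 rose and 1 fell, 12 and 1 when adjusted over the list alone (camera adjusted p = 1.84e-06, and adjusted p = 0.429 with an estimated correlation), with Cd209d at 3.22 and Folr2 at 2.83. Cfb and Fcna stood 4.15 and 2.93 above the median, and the growth factor Igf1 1.05 above it. Interferon response genes rose in 6 of 19 cases, 6 also when adjusted over the list alone (camera adjusted p = 0.00770, lost without CX3CR1 sort 3 or positive sort 8, and adjusted p = 0.808 with an estimated correlation), Irf7 among them at 1.70. Respiratory chain genes rose in 6 of 20 cases, 8 adjusted over the list alone (camera adjusted p = 0.000496, and adjusted p = 0.392 with an estimated correlation), as in Atp5a1, an ATP synthase subunit, at 1.07. In the same comparison skeletal muscle genes rose in 1 of 9 cases, 4 adjusted over the list alone, and erythroid genes in 2 of 6, 6 adjusted over the list alone (camera adjusted p = 0.0031 and 0.000352, and adjusted p = 0.672 for both with an estimated correlation). Whether RNA of other tissues had a part in the respiratory chain rise was not tested. Ctsl, Hmox1, Fcer1g and Tyrobp stood 1.58, 1.19, 0.89 and 0.71 above the median, and the plexin gene Plxnd1 1.59 below it; quantile normalization ended the call of Tyrobp.

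Against the dTomato-negative cells, single class II presentation and macrophage genes were higher in the CX3CR1 sort. H2-Aa stood at 244600 ± 18350 (SD, n = 3) against 129200 ± 8020 (SD, n = 4), Cd74, the invariant chain, at 117600 ± 32220 against 51250 ± 11620, and Cd83 at 6332 ± 1176 against 1259 ± 264. Quantile normalization ended the call of H2-Aa, with a fitted log2 fold change, not relative to the median, of 0.28 in place of 0.92 (limma adjusted p = 0.37). Adgre1, which encodes the F4/80 antigen, stood at 9528 ± 1520 against 3395 ± 405. The resident macrophage genes Lyve1 and Cd163 were lower, at 9807 ± 3688 against 24690 ± 6336 and 9888 ± 2830 against 19110 ± 4088, calls that were lost without CX3CR1 sort 1 or 3 or negative sort 5 or 7 and, for Cd163, also without CX3CR1 sort 2. Quantile normalization also ended the call of Lyve1.

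The count was 953 of 11077 genes by limma with Benjamini-Hochberg adjustment, 548 higher and 405 lower, with the median of all genes 0.29 higher. With edgeR's scaling it was 872, 307 higher and 565 lower, and log2 fold changes against the dTomato-negative sort are given relative to the median. Class II genes rose in 7 of 11 cases, 7 also when adjusted over the list alone (camera adjusted p = 0.00945, and adjusted p = 0.773 with an estimated correlation), Ciita by 1.37. Macrophage core genes rose in 8 and fell in 2 of 24 cases, 13 and 3 adjusted over the list alone (camera adjusted p = 0.00926, and adjusted p = 0.773 with an estimated correlation), Fcer1g by 1.06 and Tyrobp by 0.68. Zmynd15 and Hexb stood 2.17 and 1.56 above the median, and Tfrc 2.34 below it. Cadm1 stood 2.68 above it, a call lost without CX3CR1 sort 1.

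Of 10 tested T, B and NK cell genes, 6 were higher in the CX3CR1 sort than in positive cells and 9 when adjusted over the list alone (camera adjusted p = 0.000423, and adjusted p = 0.392 with an estimated correlation), and 5 were higher than in negative cells, or 3 when scaled to gene reads, with 9 adjusted over the list alone (camera adjusted p = 4.11e-05, and adjusted p = 0.370 with an estimated correlation). Nkg7, a cytotoxic granule gene, stood at 509 ± 213 against 6.39 ± 12.8 and 4.43 ± 6.63 in the positive and negative dTomato sorts, and the T cell kinase Lck at 201 ± 19.1 against 15.5 ± 19.4 in positive cells. Lck lost its call with any of the 3 CX3CR1 sorts or positive sort 5 or 6 left out. So did the chemokine Ccl5, at 4530 ± 1707 against 244 ± 163, with any CX3CR1 sort, positive sort 6, 7 or 8 or negative sort 8 left out. Ltb, the lymphotoxin β gene, stood at 392 ± 179 against 39.3 ± 19.3 in negative cells.

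Single clock, glucocorticoid-response and ribosomal protein genes differed between the CX3CR1 sort and both dTomato sorts; clock genes were not a list fixed beforehand and had no list test. Nr1d1, a clock repressor, stood at 15.6 ± 9.85 in the CX3CR1 sort, 549 ± 158 in positive and 1006 ± 313 in negative cells, and Nr1d2 at 16.7 ± 16.8, 402 ± 139 and 511 ± 90.0. Dbp stood at 180 ± 41.8 against 2144 ± 379 in negative cells, while the clock activator Arntl was higher, at 473 ± 130 against 77.7 ± 47.1. Glucocorticoid-response genes moved both ways: Fkbp5, a chaperone of the glucocorticoid receptor, stood 4.44 (log2) below the median against positive cells and Tsc22d3 1.60 above it, and Zbtb16 stood at 21.5 ± 2.21 against 1089 ± 533. The list had 2 genes higher and 3 lower of 12 against positive cells, 4 and 3 adjusted over the list alone, and did not pass the list test there (camera adjusted p = 0.635). Against negative cells that list had 2 genes higher and 3 lower of 12, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.0444, and adjusted p = 0.773 with an estimated correlation), which held in 4 of 11 fits with a library left out. The higher calls there were lost under all 3 other scalings, and Klf9 was among the lower ones. Per1, with 1517 ± 49.0 in the CX3CR1 sort against 674 ± 206 and 767 ± 408, lost both calls with any of the 3 CX3CR1 sorts left out, and either call without sort 5 or 6 of the dTomato group compared. Ribosomal protein genes went in both directions, 2 higher and 6 lower of 21 against positive cells (camera adjusted p = 0.0127, and adjusted p = 0.844 with an estimated correlation) and 3 higher and 5 lower against negative cells, where the other scalings gave 2 higher and 7 or 8 lower (camera adjusted p = 0.0116, and adjusted p = 0.773 with an estimated correlation). Adjusted over the list alone, these were 3 and 7 in both comparisons, and the list tests were lost without sort 8 of the dTomato group compared. Rps4x stood at 83.1 ± 19.3 in the CX3CR1 sort against 1051 ± 348 and 1114 ± 183, Rpl39 at 49.4 ± 13.4 against 742 ± 418 and 766 ± 256, and Rps11 and Rps8 were also lower. Rpl10 and Rpl4 were higher, at 955 ± 94.6 against 311 ± 58.7 and 313 ± 21.4, and at 17960 ± 1893 against 8959 ± 2037 and 9641 ± 802. Ribosomal protein genes have many processed copies that can share reads, so single values are uncertain. The ribosomal RNA precursor Rn45s took 0.0916% to 0.147% of gene reads in the CX3CR1 sort and 0.670% to 4.43% in the dTomato sorts. Counts of called genes fell by over 1.5 times without any CX3CR1 sort, to 871, 692 and 696 against positive cells and to 428, 509 and 435 against negative cells, without sorts 1, 2 and 3 in turn. Mouse line, gate and library set change together here and cannot be told apart.

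**Figure D2:**
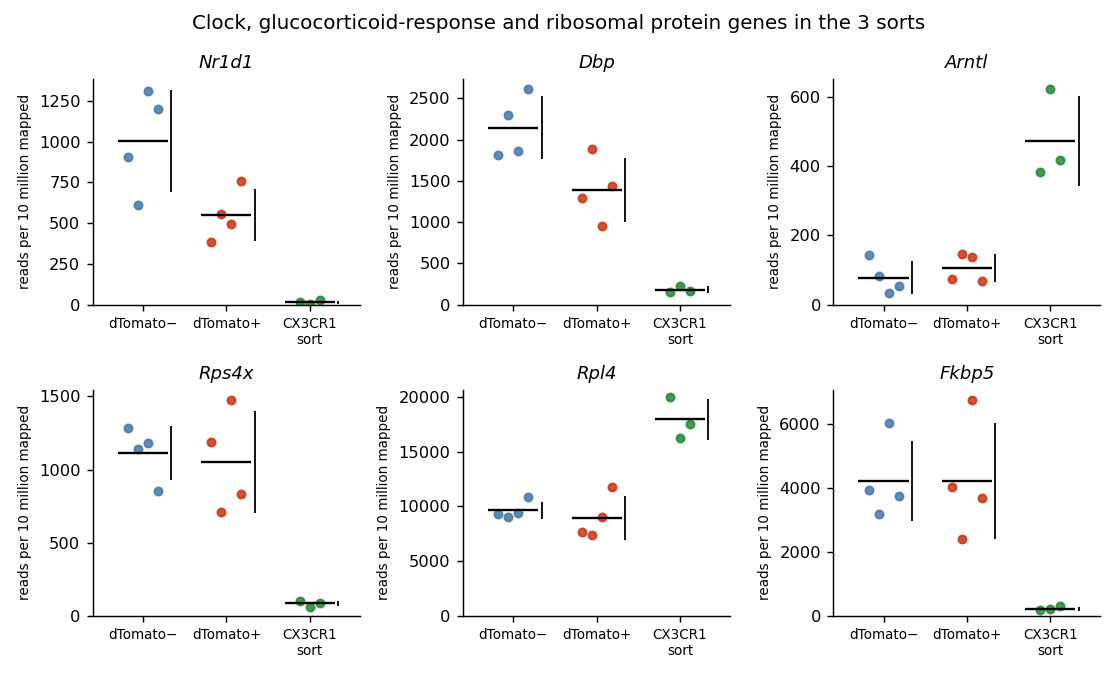
Reads per 10000000 mapped reads (vertical axes, linear) of 6 genes in the 3 sorts; points are libraries, horizontal lines means and vertical lines ± 1 SD (n = 4, 4 and 3). Nr1d1, Dbp, Rps4x and Fkbp5 lie lower, and Arntl and Rpl4 higher, in the CX3CR1 sort than in both dTomato sorts.

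The HA immunoprecipitate against whole-tissue input asks which transcripts sit on tagged ribosomes of Cx3cr1-expressing cells. Single macrophage transcripts were higher in the immunoprecipitates: C1qa, a complement component, stood at 7707 ± 2740 (SD, n = 7) against 1415 ± 99.2 (SD, n = 7), Lyz2 at 1088 ± 376 against 184 ± 46.7, and H2-Ab1 at 7995 ± 4604 against 529 ± 124. Lower were Adipoq, the adiponectin gene, at 771 ± 354 against 16580 ± 1999, and Cidea, a lipid droplet gene of brown fat, at 20690 ± 6483 against 109400 ± 11930. Cidea was still among the abundant transcripts of the precipitates. Plxna4 stood at 127 ± 62.3 against 17.9 ± 7.99, the latter from 1 to 3 reads in each input.

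By limma with Benjamini-Hochberg adjustment 5233 of 7811 genes differed, 1694 higher and 3539 lower. The share of mapped reads that lay in genes was 32.0% to 57.4% in the immunoprecipitates and 78.1% to 81.6% in the inputs, and the median of all genes lay at -0.56 (log2). The balance followed the scaling: edgeR called 5386, 2774 higher and 2612 lower, quantile normalization 4952, 2343 higher and 2609 lower, and scaling to gene reads 5190, 3596 higher and 1594 lower. Fold changes in log2 for this comparison are therefore given relative to the median gene.

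Of 21 macrophage core genes 19 rose, 19 also when adjusted over the list alone (camera adjusted p = 6.38e-09, and adjusted p = 0.192 with an estimated correlation). C1qa stood 2.89, Lyz2 3.02, Aif1 3.30 and Laptm5 2.34 above the median. All 8 tested class II genes rose, 8 also adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.195 with an estimated correlation), H2-Ab1 by 4.22, H2-DMb1 by 2.95, H2-Eb1 by 2.69 and Cd74 by 2.48. Alternative activation genes rose in 9 of 11 cases, 9 adjusted over the list alone (camera adjusted p = 0.000168, and adjusted p = 0.353 with an estimated correlation), with the lectin Mgl2 at 3.03 and the scavenger receptor Stab1 at 2.67. Cx3cr1 stood at 150 ± 43.7 against 77.3 ± 40.3, 1.62 above the median; its call (limma adjusted p = 0.0146) was lost without wild-type input 2 and within either genotype alone.

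Respiratory chain genes fell in 18 of 20 cases, with 18 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000143, and adjusted p = 0.810 with an estimated correlation), as in Cox5b at -2.48 and Atp5b at -2.07. Cytoplasmic ribosomal protein genes fell in 16 of 17 cases, 16 adjusted over the list alone (camera adjusted p = 8.68e-05, and adjusted p = 0.606 with an estimated correlation), with Rplp1 at -1.90 and Rplp0 at -1.77. The other scalings called fewer: 12 respiratory chain genes lower and 3 higher under quantile normalization, 15 and 3 with gene reads and 16 and 1 by edgeR, and ribosomal protein genes 12 lower and 1 higher, 11 and 1, and 14 and 0. General adipocyte genes had 10 lower and 1 higher of 14, the same numbers adjusted over the list alone (camera adjusted p = 0.0437, lost without wild-type immunoprecipitate 3, knockout immunoprecipitate 1 or 3 or knockout input 4, and adjusted p = 0.840 with an estimated correlation), Adipoq at -4.09 and Cfd at -2.24. The thermogenic list was mixed, 6 higher and 5 lower of 16 with the same numbers adjusted over the list alone, and did not pass the list test (camera adjusted p = 0.601). It had 10 higher and 5 lower under quantile and gene-read scaling and 9 and 5 by edgeR. Cox8b stood at -3.01 and Cidea at -1.94, but Ppara, a nuclear receptor of fatty acid oxidation, at 2.21. All 7 erythroid genes fell, 7 also adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.810 with an estimated correlation), among them Hba-a1, which shares reads with its copy, at -1.02. Quantile normalization called 5 of them lower, scaling to gene reads 6 and edgeR 7. The ferritin gene Fth1 and the nucleotide kinase gene Nme2 stood at -3.62 and -4.26.

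Of 14 plexin, semaphorin and neuropilin genes 4 rose and 2 fell, and the list test missed the threshold (camera adjusted p = 0.0568). The counts depended on the scaling, with 10 higher and 0 lower when scaled to gene reads, 10 and 2 by edgeR and 5 and 1 after quantile normalization. Plxna4 stood 3.18, Nrp1 2.44 and Plxnd1 2.01 above the median, and Plxna1 0.86 below it, a call lost when scaled to gene reads. Vegfa and Pdgfb stood 2.17 and 2.48 above it. Kdr, an endothelial receptor, and Rgs5, a pericyte gene, stood at 3.22 and 3.72, but their lists did not pass. Under the deposited scaling endothelial genes had 5 higher and 4 lower of 12, 5 and 5 adjusted over the list alone (camera adjusted p = 0.568), and smooth muscle and pericyte genes 4 higher and 4 lower of 10, the same adjusted over the list alone (camera adjusted p = 0.609). Endothelial genes had 6 higher and 1 lower with gene reads and 5 and 2 by edgeR and quantile normalization, smooth muscle and pericyte genes 5 and 2 under all 3, and the medians of both lists changed sign with the scaling. Nuclear noncoding RNAs rose in all 4 cases, 4 adjusted over the list alone (camera adjusted p = 0.000885, and adjusted p = 0.192 with an estimated correlation), Malat1 by 3.19 and Neat1 by 2.08. Rn45s stood 7.81 above the median and took 6.03% to 23.1% of gene reads in the immunoprecipitates against at most 0.150% in the inputs, and Lars2 stood 6.44 above it.

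The IgG control of knockout sample 1 gives the background of the pull-down in 1 library without replicates, so its ratios describe these libraries only. Its title names IgG while its antibody label names the HA tag. Class II genes had a median log2 ratio of immunoprecipitate to IgG of 4.27 over 7 genes and macrophage core genes of 2.81 over 19, each at the 100th percentile of 10000 random lists matched on expression. At that percentile were also the alternative activation list at 2.56 over 9 genes and, with smaller ratios, the erythroid list at 0.80 over 7 and the ribosomal protein list at 0.72 over 16. The brown adipocyte thermogenic list stood at -0.12 over 16 genes. Lists that fell against input were also lower in IgG than in input. The respiratory chain list stood at -1.095 over 20 genes, general adipocyte at -0.95 over 14 and ribosomal protein at -1.52 over 16. Immunoprecipitate to IgG was 0.07 for respiratory chain genes (48.7th percentile) and -0.05 for general adipocyte genes (14.1th percentile). Falls of these lists against input thus did not stand clear of IgG in these libraries. The plexin, semaphorin and neuropilin list stood at 0.03 over 13 genes (44.1th percentile), and at 0.98 for IgG to input (96.6th percentile), and the growth and neurotrophic factor list at 0.12 over 6 genes (63.7th percentile), so neither stood clear of IgG in these libraries. Among single genes outside the macrophage lists, Vegfa was at 0.994-fold of IgG, Ppara at 0.989-fold, Pdgfb at 1.13-fold and Plxna1 at 1.02-fold. Nrp1, Kdr and Rgs5 lay lower at 0.605-fold, 0.476-fold and 0.649-fold, while Plxnd1 lay at 1.48-fold (lower end of the exact 95% interval 1.10, counting error only) and Lars2 at 4529 against 2063. Across 6710 genes, which are not independent replicates, the immunoprecipitates correlated with the IgG library at Pearson 0.713 to 0.919 and the inputs at 0.627 to 0.689. H2-Ab1 stood at 10873 against 834 in the IgG library and C1qa at 11601 against 926, Aif1, Cd74, Mgl2, Cx3cr1 and Stab1 were 53.8-fold, 19.6-fold, 17.5-fold, 5.69-fold and 2.73-fold above it, while the ratios of Cidea and Adipoq were 1.04-fold and 0.971-fold. Plxna4 was 4.23-fold above IgG, from 29 against 9 reads (exact 95% interval 1.95 to 10.2, counting error only), and Mecp2 0.984-fold, from 9 against 12 reads. Rn45s took 4.86% of the gene reads of the IgG library, and Malat1 lay at 0.489-fold in the immunoprecipitate relative to IgG. The nuclear noncoding list stood at -0.80 over 4 genes for immunoprecipitate to IgG (0.26th percentile). For IgG to input it stood at 5.77 (100th percentile), so its rise over input did not stand clear of IgG in these libraries.

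**Figure D3:**
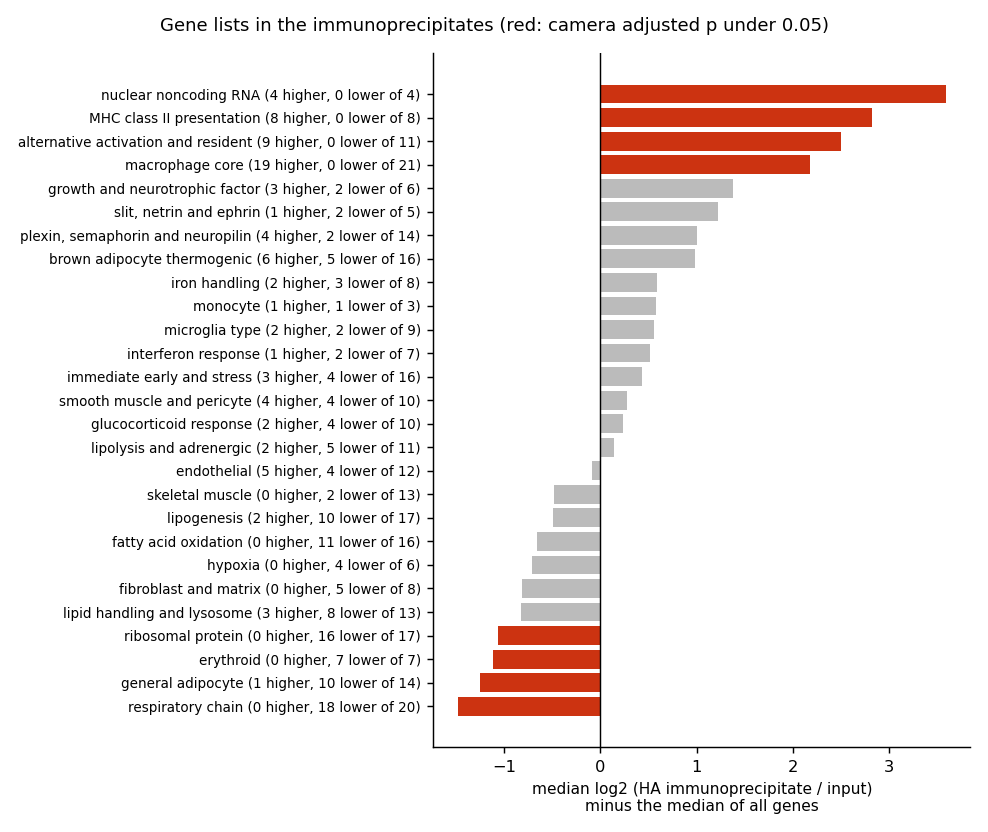
Median log2 ratio of immunoprecipitate to input of each gene list with at least 3 tested members, minus the median of all genes (horizontal axis); numbers beside each list count its members called higher or lower, and red bars mark lists with a camera adjusted p under 0.05. Nuclear noncoding RNA lies highest at 3.59 and class II presentation follows at 2.82, with the respiratory chain lowest at -1.48.

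The knockout against wild-type immunoprecipitates ask what Mecp2 loss changes in the transcripts on tagged ribosomes. Mecp2 stood at 68.1 ± 29.3 (SD, n = 4) against 322 ± 100.5 (SD, n = 3), a log2 fold change of -2.31 ± 0.52 (SE). That passed limma's test with Benjamini-Hochberg adjustment among the 4 genes fixed beforehand (adjusted p = 0.0013) and not over all genes (adjusted p = 0.168). Plxna4 stood at 161 ± 58.7 against 80.9 ± 30.1, a log2 fold change of 0.98 ± 0.51 that lay within the spread between samples (limma adjusted p = 0.349 over all genes and 0.146 over the 4 fixed genes). Cx3cr1 did not separate the genotypes, at 143 ± 37.2 against 159 ± 58.6.

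Over all 6730 genes limma with Benjamini-Hochberg adjustment called 3, all higher in the knockout. These were Nme2 at 569 ± 46.0 against 97.5 ± 54.8, Fth1 at 5794 ± 1076 against 1215 ± 622, and Suclg1, a citric acid cycle enzyme subunit, at 1691 ± 606 against 345 ± 130, with adjusted p of 0.037, 0.0434 and 0.0434. The deposited scaling put the median of all genes 0.49 higher (log2) in the knockout, and relative to it the 3 stood 2.18, 1.87 and 1.81 higher. Nme2 and Fth1 were low in the immunoprecipitates against input, at -4.26 and -3.62 (log2) relative to the median gene. Whether tissue background in the immunoprecipitates differed between the genotypes was not tested. The count depended on the fit, with 392 when all 14 libraries entered, 34 by DESeq2, 21 without the filter on low genes, 7 after quantile normalization and 4 by edgeR. It also hung on single libraries: it was 0 with any of knockout immunoprecipitates 1 to 4 or wild-type 2 or 3 left out, and 837, 832 of them higher, without wild-type 1. An unadjusted p under 0.05 was reached by 1072 genes, and 718 genes (10.7%) did not overlap between genotypes, where chance gives 5.714% on average. Genes do not vary independently, and the shift of the median by 0.49 enters that share, so it shows no excess over chance.

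By camera at the preset correlation 10 lists passed the threshold in the immunoprecipitates, and none with an estimated correlation (adjusted p = 0.821 for each). Respiratory chain genes, with 0 of 20 calls and 6 higher when adjusted over the list alone (camera adjusted p = 9.25e-05), were the list that passed with each of the 7 libraries left out, Atp5b at 16640 ± 4716 against 6017 ± 2748. In knockout sample 1 that list stood at 0.07 (log2) for immunoprecipitate to IgG (48.7th percentile), not clear of IgG. Whether its genotype difference lies in the background of the pull-down was not tested. Macrophage core genes had 0 of 20 calls and 4 adjusted over the list alone, class II genes 0 of 8 and 4 (camera adjusted p = 0.0158 for both). The macrophage list was lost without knockout 2 or wild-type 1 (adjusted p up to 0.623) and the class II list without wild-type 1 or 2 (up to 0.286). A wider set of 357 macrophage-restricted transcripts, chosen from the sorts and the wild-type inputs, stood 0.19 ± 0.24 (log2, SE) higher in the knockout relative to the median gene, within the error (exact permutation p = 0.429, two-sided). Lists of other cells and functions moved too. Endothelial genes (0 of 12 calls, 0 adjusted over the list alone, camera adjusted p = 0.0268), erythroid genes (0 of 7, 2, 0.0339), fatty acid oxidation genes (0 of 16, 1, 0.0329) and iron handling genes (1 of 6, 3, 0.0329) lay higher relative to other genes. Skeletal muscle genes (0 of 13, 0, 0.00437) and glucocorticoid-response genes (0 of 10, 0, 0.0408) lay lower. Each of these 6 lists and the nuclear noncoding list was lost in at least 2 of the 7 fits with a library left out, wild-type 1 or 2 among them. Named members were C1qa at 9024 ± 2781 against 5950 ± 1681, C1qb at 4926 ± 1301 against 2258 ± 1334, H2-Aa at 10090 ± 4302 against 3493 ± 1236 and H2-Ab1 at 10650 ± 4295 against 4457 ± 1752. Relative to the median gene their log2 fold changes were 0.09, 0.75, 0.98 and 0.74, and that of Mgl2 was 1.33. Apoe and the lipogenic enzyme gene Fasn stood at 19170 ± 6507 against 7636 ± 2593 and 70660 ± 33230 against 27040 ± 30600. The chaperone gene Hspa8 stood at 3580 ± 759 against 1564 ± 279 and the capillary gene Gpihbp1 at 1346 ± 632 against 531 ± 156. Nuclear noncoding RNAs had 0 of 4 calls and 0 adjusted over the list alone, and lay lower relative to other genes (camera adjusted p = 0.0158), Malat1 at 17430 ± 4852 against 31530 ± 1185. Nrp1, Vegfa and Cidea differed by log2 fold changes of -0.19, -0.41 and -0.12 relative to the median gene. The share of mapped reads in genes was 34.6% to 57.4% in knockout and 32.0% to 49.6% in wild-type immunoprecipitates.

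**Figure D4:**
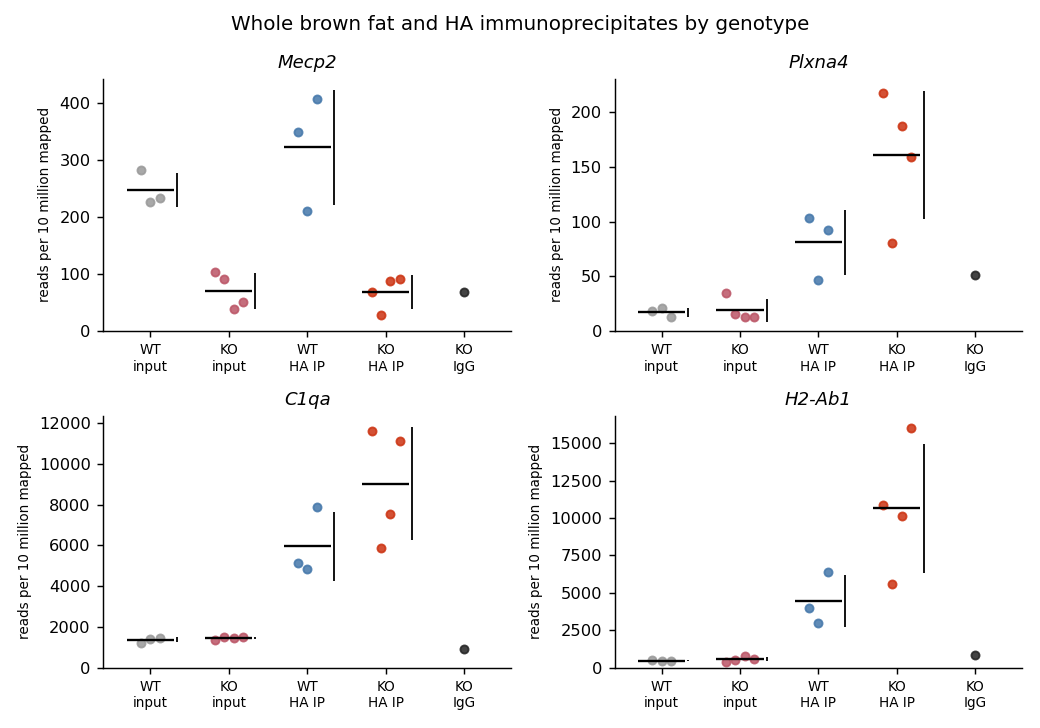
Reads per 10000000 mapped reads (vertical axes, linear) of Mecp2, Plxna4, C1qa and H2-Ab1 in each input, HA immunoprecipitate and the IgG library; points are libraries, horizontal lines means and vertical lines ± 1 SD (n = 3 wild type, 4 knockout, 1 IgG with no error). Mecp2 lies lower in knockout than in wild-type libraries of both fractions, and C1qa, H2-Ab1 and Plxna4 lie higher in the immunoprecipitates than in the inputs.

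The same genotypes in the input show whole brown fat. Mecp2 was low here too, at 70.3 ± 31.6 (SD, n = 4) against 247 ± 30.7 (SD, n = 3), a log2 fold change of -1.91 ± 0.45 (SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.00112 over the fixed genes tested and 0.215 over all genes). Trf, the iron carrier transferrin, fell 3.43-fold to 540 ± 172 from 1782 ± 218, and Retn, the adipokine resistin, fell 2.36-fold to 693 ± 151 from 1618 ± 233. The brown fat transcripts Cidea and Cox8b differed by less than the spread between samples, with Cidea at 106300 ± 4719 against 113700 ± 18610 and Cox8b at 85690 ± 10680 against 83940 ± 11010. C1qa and H2-Aa stood at 1452 ± 62.7 against 1364 ± 130 and at 2002 ± 204 against 1814 ± 316.

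Trf and Retn were the 2 calls among 5760 genes (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0065 and 0.0404), and 415 genes reached an unadjusted p under 0.05. The call of Trf was lost without knockout input 2 and that of Retn without knockout input 1, 2 or 3 or wild-type input 2 or 3. The count was 10 without the filter on low genes, 12 by DESeq2, 4 after quantile normalization and 0 with all 14 libraries in the fit (227 genes at an unadjusted p under 0.05). It was 66 without wild-type input 1, 0 without knockout input 2, 5 without knockout input 4, and 1 without knockout input 3 or wild-type input 2 or 3. By camera at the preset correlation 7 lists passed, and none with an estimated correlation (adjusted p = 0.601 for each). Skeletal muscle genes had 0 of 12 calls and 0 adjusted over the list alone, and lay lower in the knockout (camera adjusted p = 0.00502, lost without knockout input 3 or wild-type input 1), with Acta1 at 6251 ± 6369 against 8663 ± 4659. Glucocorticoid-response genes had 0 of 9 calls and 3 lower when adjusted over the list alone (camera adjusted p = 0.0209, lost without wild-type input 3), as in the metallothioneins Mt1 and Mt2 at 10850 ± 641 against 17050 ± 4351 and 5437 ± 1178 against 11290 ± 3112. Macrophage core, lipogenesis and respiratory chain genes lay higher and general adipocyte and ribosomal protein genes lower (camera adjusted p = 0.0367 for each), and each of these was lost in at least 2 of the 7 fits with a library left out. Fasn and Atp5b stood at 115500 ± 42390 against 86300 ± 35780 and 65060 ± 6183 against 53810 ± 5949.

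The difference between the genotype effects in the immunoprecipitate and in the input was tested by itself. For Mecp2 it was -0.40 ± 0.68 (log2 ± SE, limma with Benjamini-Hochberg adjustment, adjusted p = 0.783) and for Plxna4 0.94 ± 1.02 (adjusted p = 0.678), both within the error. Plxna4 had 1 to 3 reads in each input, so its difference holds little information. The median of all genes lay at 0.59. Cd74, Apoe and H2-Aa had differences of 1.86 ± 0.45, 1.83 ± 0.50 and 1.32 ± 0.51, and Fth1 stood 1.25 ± 0.43 above the median; none passed (limma adjusted p = 0.332, 0.390, 0.447 and 0.332). limma called 0 of 7811 genes, with 820 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0 as well; without wild-type immunoprecipitate 1 limma called 390, all higher, and edgeR 0.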

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

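Tests of scaling to all mapped reads and of more macrophage RNA in the knockout tissue, and the fits without wild-type immunoprecipitate 1 in edgeR or after quantile normalization, were chosen after the results were seen. In groups of 4, 212 sets of values were checked for a library apart from the other 3 by Dixon's ratio at its 95% critical value, which chance exceeds in about 1 of 20 sets, and 13 exceeded it. In dTomato-positive sorts these were Cd79b in sort 5 (807 against 666 to 670), H2-Aa and H2-Eb1 in sort 8 (337760 against 234550 to 244140 and 179690 against 106690 to 112380), Irf8 in sort 6 (4436 against 2723 to 3003) and Nkg7 in sort 8 (25.6 against 0). In dTomato-negative sorts they were Ltb in sort 7 (68.2 against 28.6 to 30.7) and, in sort 8, Rpl39 (385 against 852 to 926) and Rps11 (3940 against 1993 to 2094). In knockout inputs they were Cidea in input 2 (99233 against 108200 to 109400), the share of mapped reads in genes in input 2 (78.4% against 80.9% to 81.2%), Mt1 and Rn45s in input 4 (11799 against 10425 to 10621 and 7398 against 2442 to 2788), and Plxna4 in input 1 (34.6, from 2 reads, against 1 read in each other knockout input).

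Outside the comparisons, the IgG library held more than any input of 7 of the 11 transcripts looked at: Rn45s at 260660 (inputs 908 to 11732), Malat1 at 27578 (2352 to 5435), Plxna4 at 51.4 from 9 reads (at most 34.6), and the Y-linked genes Ddx3y at 1028 (at most 34.6), Eif2s3y at 240.0 (at most 34.6), Uty at 109 (at most 35.3) and Kdm5d at 39.99 (at most 26.4). The HA immunoprecipitates also held more Ddx3y than any input, at 332 to 1047 in knockout and 234 to 1008 in wild-type libraries. Eif2s3y stood at 112 to 289 and 129 to 199 there, also above every input. For Uty and Kdm5d the immunoprecipitates overlapped the inputs. The excess of Ddx3y and Eif2s3y over input was thus not particular to the IgG library. The genotype effect differed between immunoprecipitate and input for 6 gene lists by camera at a preset correlation: iron handling and ribosomal protein (adjusted p = 0.00428 for each), respiratory chain (0.00576), fibroblast and matrix (0.0202), and class II presentation and endothelial genes (0.0233 for each). None held with an estimated correlation (adjusted p = 0.974), no member of these lists was called by limma, and each list was lost without wild-type immunoprecipitate 1, 2 or both in turn.

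Other splits of the same libraries test whether the counts of called genes could come from any grouping. The real split gave the highest count, as 1 of the splits drawn, in the dTomato sorts (220 genes against at most 2 in 35 splits). So it did in the CX3CR1 sort against positive cells (1325 against at most 502 in 35) and negative cells (953 against at most 315 in 35). In immunoprecipitate against input it was also highest (5233 against at most 3564 in 100). With 35 splits the smallest share the real split can reach is 0.0286, so chance is argued against there and not excluded. For the CX3CR1 sort the real split is also that of mouse line and library set. The genotype counts do not argue against chance: 4 of 35 splits of the immunoprecipitates gave 3 genes or more, and 3 of 35 splits of the inputs gave 2 or more (highest other 8). The difference between genotype effects had 0 genes, a count that all 35 splits reach by construction, so the splits test nothing there (highest other 1014). The highest other split of the immunoprecipitates called 2383 genes, far more than the genotype, which points to a structure of the samples. It set knockout 1, 3 and 4 with wild-type 1 against knockout 2 with wild-type 2 and 3, and the last 3 are the libraries with under 40% of their reads in genes.

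Most transcripts stood higher in the knockout immunoprecipitates, with a median log2 fold change of 0.49 and, without wild-type 1, 832 of 837 calls higher. Scaling to gene reads without Rn45s brought that median to 0.0204, but such scaling centres the median whatever the source, so this decides nothing and scaling to all mapped reads stays open. Without wild-type 1 edgeR called 87 genes, 39 higher and 48 lower, and quantile normalization 149. The share of reads in genes may account for part: the median knockout minus wild-type difference was 0.18 among the 3 libraries under 40% and 0.20 among the other 4, against 0.49 over all 7, but each side holds a lone library of 1 genotype. More macrophage RNA in the knockout tissue stays open. In the knockout input 85 macrophage-restricted transcripts stood 0.11 ± 0.10 (SE) higher relative to the median gene, within the error (exact permutation p = 0.371, two-sided). These transcripts were chosen in part for low values in the same wild-type inputs, which biases the difference upward. An effect of Mecp2 on ribosome-bound RNA is also open: with the share of reads in genes as a covariate limma called 0 genes, 576 at an unadjusted p under 0.05, while the log2 fold changes of Nme2, Fth1 and Suclg1 went from 2.67 ± 0.41, 2.36 ± 0.41 and 2.30 ± 0.39 (SE) to 2.33 ± 0.37, 2.02 ± 0.32 and 2.03 ± 0.34 (limma adjusted p = 0.0786, 0.0786 and 0.0981). These 3 genes were picked as the calls of this same comparison, so fold changes beyond their errors do not speak for an effect. The covariate took a degree of freedom, so the 0 does not exclude one. A difference in tissue background between the genotypes was not tested and stays open. Nme2 and Fth1 lay low in the immunoprecipitates against input.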

How the results depend on the processing

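The fits by edgeR and DESeq2 on recovered reads, the pseudocount of 10, scaling to gene reads, centring on macrophage-restricted transcripts, the gene-share covariate and the fits without doubted libraries were chosen after the data were seen. Of 138 calls of single genes followed through the settings the direction held in every setting, and none reversed. These were calls of the main fit, picked in part for groups that do not overlap. Leaving out a library can hardly reverse such genes, so this says little about stability. In the dTomato sorts 23 of 32 called genes kept their call in every setting, against positive cells 28 of 33 and negative cells 22 of 32 in the CX3CR1 sort, in immunoprecipitate against input 33 of 36, and in both genotype comparisons 0 (of 3 and 2). The cause was not tested except where fewer libraries or genes entered.

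With each library left out in turn, counts ranged from 151 to 177 (main 220) in the dTomato sorts, 692 to 1551 (1325) and 428 to 1080 (953) for the CX3CR1 sort against positive and negative cells, 5017 to 5581 (5233) for immunoprecipitate against input, 0 to 837 (3) and 0 to 66 (2) for the genotype in immunoprecipitate and input, and 0 to 390 (0) for their difference. Lists past the threshold ranged from 6 to 9 (10), 5 to 10 (7), 3 to 9 (5), 7 to 10 (8), 3 to 11 (10), 3 to 8 (7) and 2 to 8 (6) in the same order. They moved by over 1.5 times in the dTomato sorts without negative sort 7 (6), against negative cells without CX3CR1 sort 2 (9) or negative sort 8 (3), for the genotype in the immunoprecipitate without wild-type 1 (5) or 2 (3), in the input without knockout 3 (4) or wild-type 1 (4) or 3 (3), and for the difference without wild-type immunoprecipitate 1 (2) or 2 (3) or wild-type input 1 (3). With an estimated correlation these lists became 1, 0, 0, 0, 0, 0 and 0, and with fry 4 in the dTomato sorts, 3 against negative cells, 19 in immunoprecipitate against input and 0 in the 3 genotype tests.

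DESeq2 called 410 genes in the dTomato sorts, 34 for the genotype in the immunoprecipitate and 12 in the input. Without CX3CR1 sort 1 and the shallowest dTomato sort of the group compared (positive 6 or negative 5), the CX3CR1 sort gave 796 and 347 calls against positive and negative cells. For the genotype in the immunoprecipitate, quantile normalization gave 7, no filter 21, all 14 libraries in the fit 392, only genes higher in the immunoprecipitate 0, without wild-type 3 and knockout 2 0, without wild-type 1 87 by edgeR and 149 after quantile normalization, centring on macrophage-restricted transcripts 0 and the share of reads in genes as a covariate 0. For the input, quantile normalization gave 4, no filter 10 and all 14 libraries 0. For the difference, quantile normalization and scaling to gene reads gave 1 each.

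The titles number samples together, input and immunoprecipitate with letters, without saying that they share an animal, and the number was not taken as a pairing: correlations of deviations of same-numbered samples were 0.00953 to 0.148 in the dTomato sorts, 0.051 to 0.161 in wild-type and 0.085 to 0.298 in knockout libraries, not all over 0.1. As a hint from the data, all 7 immunoprecipitates and 3 of 4 dTomato-positive sorts correlated best with their own number. With the replicate block limma called 314 in the dTomato sorts, 5414 in immunoprecipitate against input, 4 and 7 for the genotype in immunoprecipitate and input and 0 for the difference; edgeR with the block called 277, 5578, 10, 7 and 0. Of the genes followed, the block ended the call of Nlrp3 in the dTomato sorts. Depth limits low genes most in wild-type immunoprecipitate 3, where 3 reads correspond to 55.4.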

Other observations

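The test of Mecp2 loss restricted to macrophages and that of loss in most cells of the tissue were chosen after the values were seen, as were the patterns themselves. Transcripts of other tissues differed between the sorts. Skeletal muscle genes were lower in dTomato-positive than in negative cells in 1 of 7 cases, 1 adjusted over the list alone (camera adjusted p = 0.0478, which held in 2 of 8 fits with a library left out, and adjusted p = 0.687 with an estimated correlation), and higher in the CX3CR1 sort than in positive cells in 1 of 9, 4 adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.672 with an estimated correlation). Erythroid genes were higher in the CX3CR1 sort than in positive cells in 2 of 6 cases, 6 adjusted over the list alone (camera adjusted p = 0.000352, and adjusted p = 0.672 with an estimated correlation). Respiratory chain and interferon response genes lay lower in dTomato-positive than in negative cells with 0 of 20 and 0 of 18 calls and none adjusted over the lists alone (camera adjusted p = 0.00265 and 0.00867, and adjusted p = 0.271 and 0.687 with an estimated correlation); interferon genes were lost without positive sort 7 or negative sort 6.

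Mecp2 was lower by 177 ± 23.7 (SE) reads per 10000000 mapped reads in the knockout than in the wild-type input, although the input is whole tissue. The sorts held 509 on average, and the input to sort ratio of 23 macrophage core genes had a median of 1.60% and a highest value of 15.6% (Cx3cr1). At that highest ratio macrophages would bring at most 79.5 to the input, and 8.15 at the median, so a loss restricted to macrophages does not reach the measured fall; the tables were scaled separately, and the sorts come from other mice. Depth is argued against, since of the 200 genes nearest in level 0% had a fold as low. A loss in most cells of the tissue is a candidate explanation, with a log2 fold change of -1.91 in the input, from 3 to 6 reads in each knockout input. The fold change in the immunoprecipitate differed from it by -0.40 ± 0.68, or by -0.99 relative to the median of all genes. That comparison cannot decide, since the immunoprecipitates correlated with the IgG library at Pearson 0.713 to 0.919. Their Mecp2 fold change may thus come in part from tissue background.

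Ribosomal protein genes as a set, and single clock genes, differed between the CX3CR1 sort and both dTomato sorts. Over 80 tested Rpl and Rps genes the median absolute log2 fold change was 0.67 against positive cells, with 9 higher and 25 lower, and 0.78 against negative cells, with 10 higher and 21 lower; these lay at the 99.71st and 100th percentiles of 10000 expression-matched lists, whereas between the dTomato sorts it was 0.13 and lay at percentile 0 with no calls. Reads shared between near-identical copies and counted differently in the library sets would give such moves in both directions. The 80 genes include those whose moves raised the question, so this cannot decide. A difference between mouse lines was not tested. A different time of collection stays open for the clock genes. Of 10 clock genes not looked at before, 8 could be tested and 6 went in the predicted direction in each comparison. Against positive cells Tef stood at -1.32 ± 0.27 (SE) and Cry1 at 5.37 ± 1.51, as fitted log2 fold changes not relative to the median. Clock and Bhlhe41 went the other way in both comparisons. Past the threshold were 3 of the 8 against positive cells and 1, Tef, against negative cells (limma adjusted p = 0.00104), where Cry1 and Per3 missed it (adjusted p = 0.172 and 0.793). Per1, a clock gene named above with the glucocorticoid-response genes, was not among the 10. It stood higher in the CX3CR1 sort, at 1.22 ± 0.33 and 1.14 ± 0.33 against positive and negative cells, not relative to the median. Per2 and Per3 stood lower. The calls of Per1 were lost with any CX3CR1 sort left out. Collection time, line and library set are confounded.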
